A study of Mus musculus with 6 samples.

How the data were processed

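Total RNA from the intermolar eminence of the mouse tongue at the embryonic stage E17.5 was sequenced in 6 libraries, 3 WT and 3 labelled Fst-KO. Per the labels' protocols, freshly dissected tissue was homogenised in TRIzol, RNA was extracted with RNeasy columns, samples with an RNA integrity number above 7 were used, and libraries followed standard Illumina protocols. Whether the libraries mark strand is not given in the sources used here.

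The single file is the authors' own comparison of mutant against WT, called the authors' deposited table in the report. Per the submitters' processing notes, the authors used BWA 0.7.12 and Partek with the mouse build mm10. Per the series' design text, reads that passed quality filters were aligned, annotated and normalised, and differences were tested with Partek's gene-specific analysis (GSA). The annotation, the normalisation, the read counting and the settings of the test are not given in the sources used here. BWA does not split a read across an intron, so reads over exon junctions can be lost or shortened, in both groups alike. Reads shared by near-identical genes can be divided in ways the table does not show.

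The columns used were the following. The p-values and the FDR are the authors', per the file headers, and the FDR equalled a Benjamini-Hochberg adjustment of the p column for all 15648 genes, within a relative tolerance of 1e-06. The ratio is the authors' quotient of mutant over WT, per the file headers, and equalled the quotient of the group means for all 15648 genes. The group means are a normalised signal that the authors made, per the file headers a least-squares mean, and their scale is not given. A column of totals, in spite of its header, holds normalised values: it equalled 3 times the sum of both group means for all 15648 genes, so each group mean is a plain mean of 3 libraries. The listed values sum to 672618 in the mean of the libraries labelled Fst-KO and 632024 in that of WT, a difference of 6.42%. The 25 most abundant genes hold 15.4% of the WT sum and 13.9% of the other. After both sums were made equal without the most abundant 156 genes, the median ratio was 1.04. The smallest geometric mean of the 2 groups was 1.01, so genes that are low in both groups are not listed here, and genes near 0 in a single group can be missing too. The table calls the mutant group "mutant", which was taken as the group titled Fst-KO since the series holds no other mutant.

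No value per library is in the table. The test written for counts or for values per library was therefore replaced, as fixed before the data were examined, by the deposited FDR under 0.05. The depth per library is unknown, no interval could be given for any mean, replicates could not be compared with each other, and no exact test between groups could be run. With 3 libraries per group, an exact permutation test of a single gene could not go below 0.1 in any case. Because the median ratio of all genes lay 0.18 above 0 on the log2 scale, ratios were also given relative to that median.

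The 28 gene lists were fixed before the data were examined. They hold 585 entries, of which 469 are in the table by symbol, and 27 lists have at least 3 genes there. For each, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn to match the list in 20 bins of mean expression. A list was called outside when it lay beyond the central 95%. Counts over the list alone use a Benjamini-Hochberg adjustment of the deposited p-values of its members. On simulated lists of 20 genes drawn from the 15648 genes of this comparison, 5% of unchanged lists lay outside, 82% of lists raised 1.1-fold were found, and 100% of those raised 1.25-fold, 1.5-fold or 2-fold. In simulated p-values for as many genes the adjustment called 100% of the changed genes, with 3.85% of calls false. The changed genes had been given p-values so low that all had to pass. The simulation thus checks the adjustment alone and is no measure of sensitivity in these data. The lists were simulated by random draws, so the 5% holds for genes that vary independently and says nothing of genes that vary together. A further 7 lists, used in the closing section, were written after the table had been seen.

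The genes named were Fst, the 15 genes past the FDR, and the 10 highest and 10 lowest ratios among genes with a mean at or above the median of all genes (16.1). Since fewer than 20 genes passed, that ranking used an unadjusted p under 0.05. From each list up to 4 members with an unadjusted p under 0.05 and the largest differences were named, or the 2 most abundant where fewer than 2 had one. Predicted genes, clone names and the like (2687 of the 15648) were counted but not named. A few single genes that this rule would name are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Positions are from GENCODE M21 on GRCm38, the assembly that mm10 names, in which 15058 symbols (96.2%) matched 1 gene. Fam26e was not matched.

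Alternatives were other thresholds, a 2-fold minimum, the adjustment recomputed, abundant genes only, the mean in place of the median, unmatched random lists, centring on the median of all genes, and pseudocounts of 0.1, 1 and 10 added to both group means. The pseudocount of 1 and the unadjusted p under 0.01 were added after the data were seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.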

Results

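RNA was sequenced from the intermolar eminence of the mouse tongue, the raised region of the dorsal tongue that lies between the molars, at the embryonic stage E17.5. The mice were C57BL/6. The labels give 3 wild-type (WT) libraries and 3 libraries from mutants of Fst, the gene for follistatin, a secreted protein that binds activins and some bone morphogenetic proteins (BMPs). The labels call the tissue tongue epithelium, while the extraction protocol speaks of dissected tissue. The values come from the authors' deposited table, which lists 15648 genes with a mean normalised value per group, the ratio of the group means, a p-value and an FDR. It gives no value per library, so no standard deviation stands beside any mean, the number of reads per library is unknown, and no library could be set apart from the others. The p-values measure only the spread between these 6 libraries, which may be technical, because nothing in the labels says that they came from separate animals.

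Fst itself was higher in the libraries labelled Fst-KO. Its mean in the authors' deposited table was 69.7 in those libraries and 33.2 in WT, a ratio of 2.10 with a p-value of 4.31e-06 and an FDR of 0.0158. The gene lies on chromosome 13 from 114452290 to 114458951 on the minus strand (mm10). Which part of the gene the mutant allele removes is not given in the sources used here, and a value for the whole gene does not separate exons inside such a part from those outside it. Because the targeted gene went against the label, the groups are called "the libraries labelled Fst-KO" and WT throughout, and every direction is that of the labels.

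The first question was which genes differed between the groups. At an FDR under 0.05 in the authors' deposited table, 15 genes differed, of which 12 were higher and 3 lower in the libraries labelled Fst-KO. The higher genes included 5 for contractile proteins of slow or cardiac muscle and mast cell proteases, and the lower ones were Tmem72, Rxfp1 and Pcdh10. An unadjusted p under 0.05 was reached by 2437 genes, against 782.4 expected with no change, and 2097 of these were higher in the libraries labelled Fst-KO. Most genes were slightly higher in those libraries: the median ratio over all genes was 1.14 (0.18 on the log2 scale), its quartiles were 1.04 and 1.24, and 81.0% of genes had a ratio above 1. The median ratio was 1.18 in the tenth of genes with the lowest means and 1.096 in the tenth with the highest. Ratios were therefore also taken relative to the median of all genes, and all 15 genes kept their direction on that scale. The same held for the 2437 genes.

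**Figure D1:**
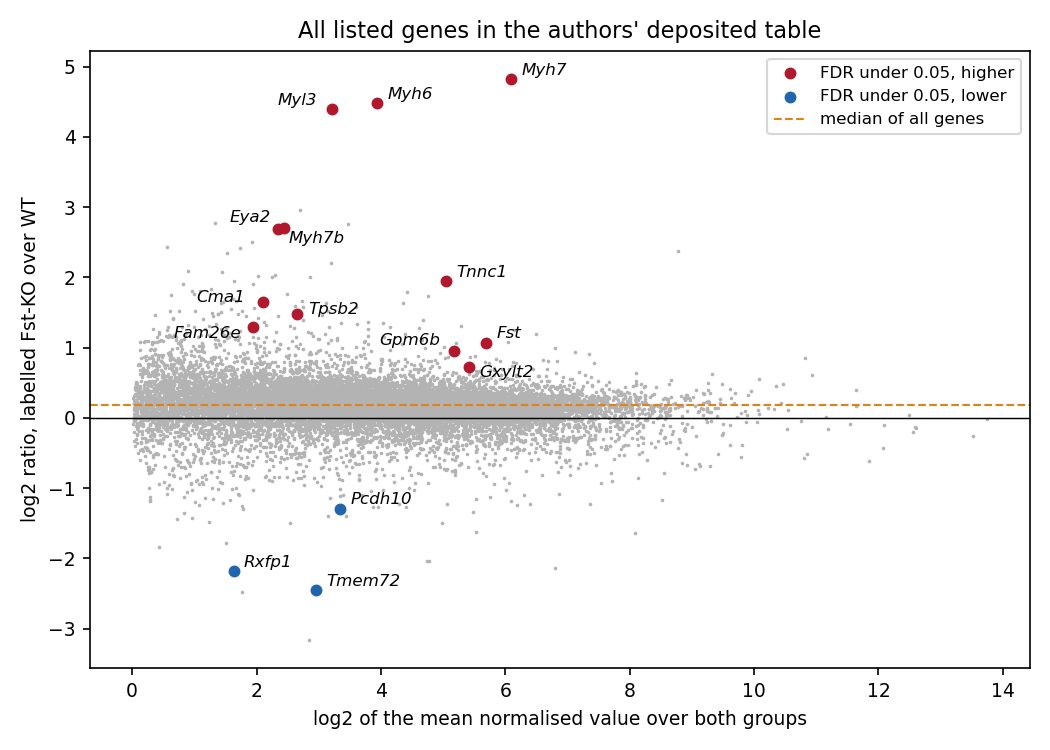
Each point is 1 of the 15648 genes in the authors' deposited table, with the log2 of its mean normalised value over both groups on the x axis and the log2 ratio of the libraries labelled Fst-KO over WT on the y axis. Red and blue points are the 12 higher and 3 lower genes with an FDR under 0.05, and the dashed line is the median of all genes at 0.18.

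Among the 12 higher genes, 5 encode contractile proteins of slow or cardiac muscle. Myh7, the slow and beta-cardiac myosin heavy chain, rose 28.4-fold, from 4.67 in WT to 132 (FDR 0.00907, authors' deposited table). Myh6, the alpha-cardiac heavy chain and the neighbour of Myh7 on chromosome 14, rose 22.3-fold, from 1.32 to 29.4, with the same FDR in the authors' deposited table. Myl3, the slow and ventricular essential light chain, rose from 0.843 to 17.7 (20.98-fold, FDR 0.0158, authors' deposited table). Tnnc1, the slow and cardiac troponin C, rose 3.86-fold and Myh7b, another slow-type heavy chain, rose 6.47-fold, with FDRs of 0.0219 and 0.0436 in the authors' deposited table. Myh6 and Myh7 are close in sequence, so reads can have been divided between them in a way that the table does not show. Relative to the median of all genes, the ratios of Myh7, Myh6, Myl3, Myh7b and Tnnc1 were 24.97, 19.6, 18.5, 5.70 and 3.39.

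The other 10 genes past the threshold were of several kinds. Eya2, a transcriptional coactivator of muscle and sensory placode development, rose 6.49-fold, from 1.44 to 9.37 (FDR 0.0219, authors' deposited table). The connective-tissue mast cell proteases Cma1 and Tpsb2 rose 3.13-fold and 2.80-fold, with FDRs of 0.0386 and 0.0436 in the authors' deposited table. Gpm6b, a membrane proteolipid of neural and other cells, rose 1.93-fold and the xylosyltransferase gene Gxylt2 rose 1.66-fold, with FDRs of 0.0219 and 0.0436 in the authors' deposited table. Fam26e rose 2.45-fold at the same FDR of 0.0436, and Fst was the remaining higher gene. Tmem72, which encodes a transmembrane protein, fell to 0.184 of WT, from 13.1 to 2.40 (FDR 0.0158, authors' deposited table). The relaxin receptor Rxfp1 fell to 0.220 of WT and the protocadherin Pcdh10 to 0.409, both with an FDR of 0.0158 in the authors' deposited table. When the p-values in the authors' deposited table were adjusted again over the 7824 genes with a mean at or above the median, 4 genes passed, all of them higher.

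**Figure D2:**
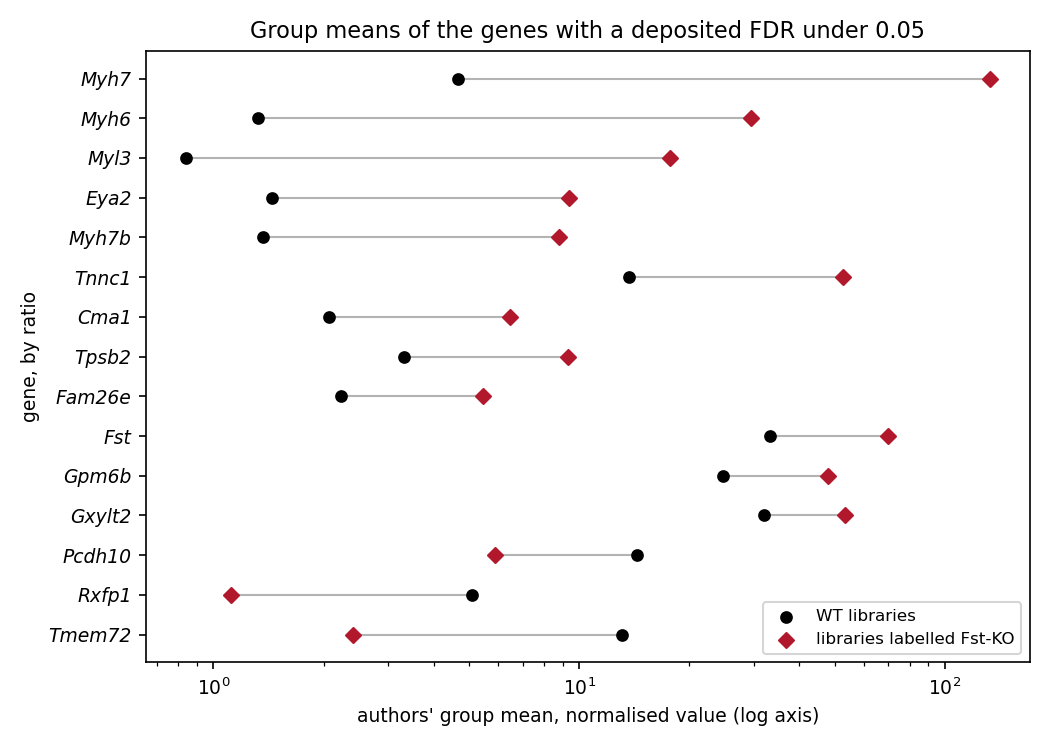
Mean normalised values in the authors' deposited table (log axis) of the 15 genes with an FDR under 0.05, ordered by ratio, with WT as black circles and the libraries labelled Fst-KO as red diamonds. No error bars are drawn because the table gives no value per library. Myh7 rose from 4.67 to 132, and Tmem72 fell from 13.1 to 2.40.

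Because fewer than 20 genes passed, the abundant genes with the largest differences were ranked among those with an unadjusted p under 0.05, as fixed before the data were examined. Besides Myh7 and Tnnc1, the genes with the highest ratios were Xist at 5.19, Mid1 at 3.45, the light chain gene Myl6b at 3.32, Tfcp2l1 at 3.09, Ltf at 2.54, Krt7 at 2.49, Arg1 at 2.37 and Anxa1 at 2.29 in the authors' deposited table. The lowest ratios in the authors' deposited table were those of Krt76 (0.228), the water channel Aqp4 (0.244), Hrnr (0.244), Tchh (0.323), Crnn (0.326), Mybpc2 (0.353), Gpd1 (0.396), Mstn (0.416), Krt24 (0.466) and Myoz1 (0.473). None of these 18 genes passed the FDR of 0.05. The lowest FDR among them was 0.0564, for Myl6b, in the authors' deposited table. The lower genes were of 2 kinds: Krt76, Hrnr, Tchh, Crnn and Krt24 belong to keratinised epithelium, and Aqp4, Mybpc2, Gpd1, Mstn and Myoz1 are expressed in fast skeletal muscle.

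The second question was how groups of genes fixed before the data were examined moved. Of 28 lists, 27 had at least 3 genes in the table. The median log2 ratio of each was placed among the medians of 10000 random lists of the same size, matched on mean expression, as a description with no p-value. By this measure 9 lists lay above and 6 below the central 95% of random lists, where 1.35 would lie outside by chance if genes varied independently. Markers of a cell type vary together between dissections and some lists share genes, so that number is no measure of chance here. The median ratios of random lists were near 1.1, so a list at 1 is low among all genes. Tnnc1, in the skeletal muscle list, was the only listed member with an FDR under 0.05 in the authors' deposited table. All other members are given as values, with the count past 0.05 when adjusted over the list alone. Of all genes with an unadjusted p under 0.05, 86.0% were higher, and no p-value was taken relative to the median of all genes. More higher than lower members in a list can therefore follow the shift of all genes.

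**Figure D3:**
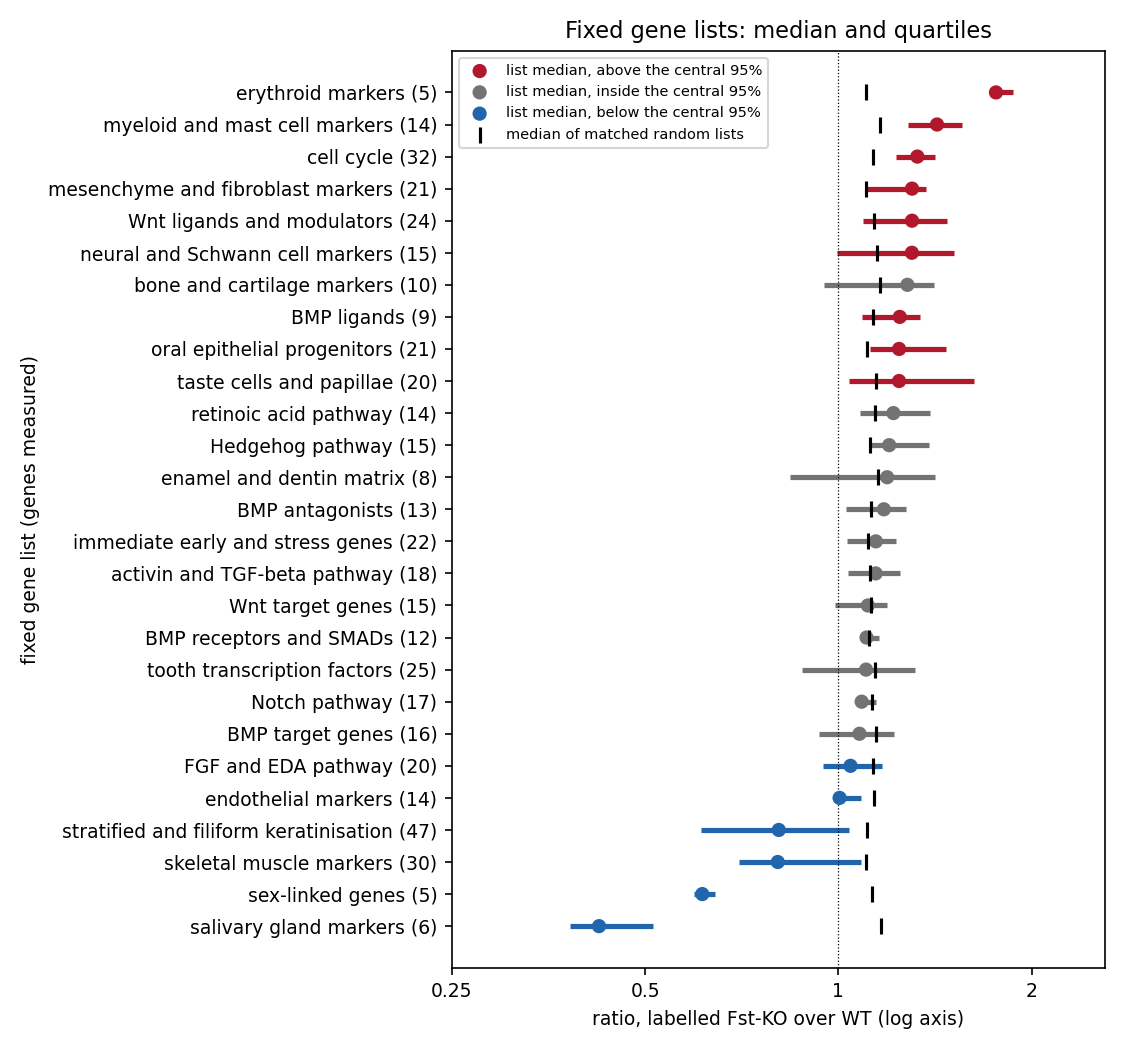
Points are the median ratio of each fixed list (libraries labelled Fst-KO over WT, log axis), bars run from the lower to the upper quartile of its genes, and black ticks are the median of matched random lists. Red and blue lists lie above and below the central 95% of 10000 random lists. Erythroid markers are highest at 1.76 and salivary gland markers lowest at 0.424.

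Skeletal muscle markers were lower as a list, although 9 of them, Tnnc1 among these, had a ratio above 1. Their median ratio was 0.805 over 30 measured genes, or 0.708 relative to the median of all genes, and lay below all 10000 random lists. At an unadjusted p under 0.05, 3 were higher, 6 were lower and 21 were neither. Adjusted over the list alone, 2 were higher (Tnnc1 and Tnnt1) and 0 lower. Slow troponins stood on the higher side, with ratios of 2.03 for Tnnt1 and 1.44 for Tnni1 in the authors' deposited table. The lower members included the perinatal myosin heavy chain Myh8, with means of 2927 against 4466 in WT and a ratio of 0.655, and calsequestrin Casq2 at 0.625 in the authors' deposited table. Tnni1 was chosen after its values were seen.

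Genes of stratified and filiform keratinisation were also lower as a list, although 16 of them had a ratio above 1 against 31 below. The median ratio of 47 measured genes was 0.808, or 0.711 relative to the median of all genes, below all 10000 random lists. At an unadjusted p under 0.05, 7 were lower and 2 higher, and 38 were neither. Adjusted over the list alone, 3 were lower and 0 higher, and these were Krt76, Hrnr and Krt24. Krt76, a keratin of the palate and gingiva, had a mean of 41.2 against 181 in WT, and Hrnr, for the cornified envelope protein hornerin, 10.8 against 44.1 in the authors' deposited table. Trichohyalin (Tchh), a protein of filiform papillae and hair, had a mean of 132 against 409, and cornulin (Crnn) 22.7 against 69.7 in the authors' deposited table. The 2 members higher at that p were Krt17 at 1.54 and Sprr2a1, one of a family of near-identical genes, at 2.80 in the authors' deposited table, both chosen after their values were seen. Krt4 and Krt13, among the most abundant members and also chosen after their values were seen, had ratios of 1.80 and 1.32 without such a p. The fall thus did not extend to all keratins of the list. The lower muscle markers and the higher mesenchyme markers moved with the same groups.

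Markers of oral epithelial progenitors were higher. The median ratio of 21 measured genes was 1.24, or 1.09 relative to the median of all genes, above all 10000 random lists. At an unadjusted p under 0.05, 8 were higher and 0 lower, and 4 of them, Lgr5, Gli1, Sox2 and Sox9, passed when adjusted over the list alone. Lgr5, a receptor for R-spondins on epithelial stem cells, had a ratio of 2.58 and Gli1, a Hedgehog target, 1.84 in the authors' deposited table. The transcription factor genes Sox2, which marks taste and dental epithelial progenitors, and Sox9 had ratios of 1.83 and 1.67, with FDRs of 0.233 and 0.0936 in the authors' deposited table. The basal keratin genes Krt5 and Krt14, chosen after their values were seen, had ratios of 1.53 and 1.47 in the authors' deposited table. Mesenchyme markers were higher in the same libraries (median 1.30) and keratinisation, skeletal muscle and salivary markers lower (0.808, 0.805 and 0.424), and mesenchyme also expresses members of this list such as Gli1 and Sox9.

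Taste cell and papilla genes were measured for 20 of 36 listed, with the same median ratio of 1.24, at percentile 99.03 of random lists. Taste receptor and transduction genes such as Gnat3, Plcb2, Tas1r2 and Tas1r3 are not in the table. At an unadjusted p under 0.05, 8 were higher and 0 lower, and 5 were higher when adjusted over the list alone. The higher members were led by keratins of simple epithelium and taste buds, with ratios of 2.49 for Krt7, 2.46 for Krt8, 2.20 for Krt18 and 2.15 for Krt19 in the authors' deposited table. Slc1a3 at 1.60 and Eya1 at 1.71 made up the 5 with Krt7, Krt8 and Krt18, and were chosen after their values were seen in the authors' deposited table. The taste transduction channel Trpm5 had means of 9.55 and 9.30, a ratio of 1.03, in the authors' deposited table. The taste receptor gene Tas1r1 had a ratio of 0.764, and the transduction genes Gnb3 and Itpr3 had 0.928 and 1.15 in the authors' deposited table. None of these taste receptor and transduction genes had an unadjusted p under 0.05, and all were chosen after their values were seen. With a pseudocount of 1 added to both means the list fell to percentile 91.14, inside the central 95%. Other epithelia also express these keratins, and in the same libraries mesenchyme and neural markers were higher (both 1.30) and keratinisation and salivary markers lower (0.808 and 0.424).

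Parts of the BMP pathway differed in where they lay. The list of BMP ligands lay just above the central 95%, with a median ratio of 1.246 over 9 genes at percentile 97.75, with 3 genes higher and 1 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. Gdf6 had a ratio of 2.27, Bmp7 1.49 and Bmp1, which in spite of its name encodes a procollagen proteinase, 1.34, and Bmp2 was lower at 0.714 in the authors' deposited table. BMP antagonists had a median of 1.18 over 13 genes at percentile 86.69, and 5 of them were higher when adjusted over the list alone. These were Grem1 at 1.80, Fstl3 at 1.44, Chrd at 1.29, Nbl1 at 1.28 and Fstl1 at 1.27 in the authors' deposited table, the last chosen after its values were seen. BMP receptors and SMADs had a median of 1.11 over 12 genes (percentile 40.05), with Bmpr1b at 1.46, Acvr1 at 1.26 and Rgma at 1.246 in the authors' deposited table as the 3 higher members at an unadjusted p under 0.05. BMP target genes had a median of 1.08 over 16 genes, 0.950 relative to the median of all genes, at percentile 6.98. Of these targets, Id2 at 1.32 and Tbx2 at 1.29 in the authors' deposited table were the 2 with an unadjusted p under 0.05. Neither of these 2 lists had a member past 0.05 when adjusted over the list alone. The BMP ligand list lay inside the central 95% with a pseudocount of 10 (percentile 92.77), with the mean in place of the median (91.06), with unmatched random lists (95.96) and over abundant genes only (96.77).

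In the activin and TGF-beta pathway the median ratio was 1.14 over 18 genes, at percentile 74.79. Adjusted over the list alone, 3 were higher and 1 lower: the TGF-beta responsive genes Pmepa1 at 1.48 and Skil at 1.28, the receptor Tgfbr2 at 1.23, and Mstn, for the muscle growth inhibitor myostatin, at 0.416 in the authors' deposited table. Tgfbr2 was chosen after its values were seen. Over abundant genes only, the list lay at percentile 99.82, but it lay at 26.55 with the mean in place of the median and at 57.62 with unmatched random lists.

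Wnt ligands and modulators were higher, with a median ratio of 1.30 over 24 genes at percentile 99.99. At an unadjusted p under 0.05, 9 were higher and 0 lower, and 1, the secreted inhibitor Sfrp1 at 1.71, passed when adjusted over the list alone in the authors' deposited table. Sfrp4 at 1.82, Dkk2 at 1.75 and Wnt10b at 1.65 followed in the authors' deposited table. The first 2 of these also encode secreted Wnt modulators. Mesenchyme, which expresses such modulators, had markers at the same median of 1.30. This list lay inside the central 95% with a pseudocount of 10 (percentile 87.81), with the mean (97.37) and over abundant genes only (93.93). Wnt target genes lay in the middle of random lists, with a median of 1.11 over 15 genes at percentile 38.09 and 1 member, Lgr5, past 0.05 when adjusted over the list alone. Tcf7 at 1.56 and Cd44 at 1.199 in the authors' deposited table were the other 2 with an unadjusted p under 0.05.

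All 15 measured Hedgehog pathway genes had a ratio above 1, and 10 lay above the median of all genes. Their median was 1.1998 at percentile 97.12, just inside the central 95%, and 6 were higher when adjusted over the list alone. Shh had a ratio of 2.31, from means of 4.09 and 1.77, and the pathway targets Gli1 and Ptch1 had 1.84 and 1.47 in the authors' deposited table. The list passed above the central 95% with a pseudocount of 1 (97.99) or 10 (99.81), with the mean (99.45) and over abundant genes only (99.84), and lay at 91.71 with unmatched random lists. Mesenchyme markers were higher in the same libraries (median 1.30).

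FGF and EDA pathway genes were low among all genes, with a median of 1.04 over 20 genes, 0.919 relative to the median of all genes, at percentile 1.19. The 4 members with an unadjusted p under 0.05 were higher, as were most genes with such a p: Fgf10 at 1.68, Edar at 1.51, Fgfr2 at 1.46 and Fgf7 at 1.32 in the authors' deposited table, with 0 past 0.05 over the list alone. The list lay inside the central 95% with a pseudocount of 10 (5.22), with the mean (26.14) and over abundant genes only (4.97). Notch pathway genes had a median of 1.09 over 17 genes at percentile 14.1, with Jag1 at 1.30, Hes1 at 1.29 and Hes6 at 1.197 in the authors' deposited table as the 3 with an unadjusted p under 0.05 and 0 past it over the list alone.

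Tooth genes are a subject of the study by the title of the series, and no listed one passed the FDR of 0.05. Tooth transcription factors had a median of 1.104 over 25 genes, 0.972 relative to the median of all genes, at percentile 18.49, and lay at 61.07 with the mean and at 83.58 over abundant genes only. Within the list 6 were higher and 0 lower at an unadjusted p under 0.05, and 5 passed when adjusted over the list alone. Barx1, a homeobox gene of molar mesenchyme, had a ratio of 2.34, from means of 7.00 and 2.99, in the authors' deposited table. Dlx1 had 2.02, Osr2 2.01, Lhx8 1.98 and Alx4, chosen after its values were seen, 1.67 in the authors' deposited table. In the same libraries mesenchyme markers were higher as well (median 1.30). Enamel and dentin matrix genes were measured for 8 of 24 listed, with a median of 1.19 at percentile 68.63. Phex at 2.31, Fam20a at 1.59 and Fam20c at 1.35 in the authors' deposited table had an unadjusted p under 0.05, and 0 passed over the list alone.

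Retinoic acid pathway genes had a median of 1.22 over 14 genes at percentile 94.19, at 98.26 with the mean in place of the median and at 72.24 over abundant genes only. Adjusted over the list alone, 3 were higher and 1 lower. Among the higher ones were the genes of the cellular retinoic acid binding proteins, with ratios of 2.28 for Crabp2 and 2.14 for Crabp1 in the authors' deposited table. The lower one was Cyp26b1, which encodes an enzyme that degrades retinoic acid, with means of 43.5 against 68.8 in WT and a ratio of 0.633 in the authors' deposited table.

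Cell cycle genes were higher almost throughout. Of 32 genes, 31 had a ratio above the median of all genes, and the list median of 1.33 (1.17 relative to all genes) lay above all 10000 random lists. Adjusted over the list alone, 25 were higher and 1 lower. The replication gene Mcm7 had a ratio of 1.61, the checkpoint kinase Bub1 1.51 and Cdc20 1.48 in the authors' deposited table. The exception was the ubiquitin-conjugating enzyme Ube2c, at 0.635, with means of 430 against 676 in the authors' deposited table. Its WT mean stood far above that of any other member, the next being Mki67 at 188, chosen after its values were seen. Whether all reads counted for Ube2c came from that gene was not tested, so its fall may not be that of a cell cycle gene. In the same libraries mesenchyme, erythroid and progenitor markers were higher (medians 1.30, 1.76 and 1.24) and skeletal muscle markers lower (0.805).

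Markers of other cell types in the tissue moved as well. Mesenchyme and fibroblast markers had a median of 1.30 over 21 genes, above all 10000 random lists, with 11 higher and 0 lower at an unadjusted p under 0.05 and 4 higher over the list alone. Thy1 at 1.60, Dpt at 1.53, Col1a1 at 1.40 and Fn1 at 1.39 in the authors' deposited table were examples. Myeloid and mast cell markers had a median of 1.42 over 14 genes at percentile 99.97, with the mast cell genes Mcpt4 at 2.87 and Cpa3 at 2.57 as the 2 that passed over the list alone in the authors' deposited table. Lyz2 at 1.78 and Ptprc at 1.59 in the authors' deposited table were among the 7 higher at an unadjusted p under 0.05, and Kit, chosen after its values were seen, was the 1 lower at 0.784. Erythroid markers had the highest list median, 1.76 over 5 genes, with Hbb-bt at 2.12, Hba-a1 at 1.87 and Hbb-bs at 1.73 in the authors' deposited table and 0 past 0.05 over the list alone. These globin genes have near-identical copies, so their single values are uncertain.

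Neural and Schwann cell markers had a median of 1.30 over 15 genes at percentile 99.22, with 3 higher at an unadjusted p under 0.05 and 0 over the list alone. Nefm had a ratio of 2.21 and Sox10 1.59 in the authors' deposited table. Over abundant genes only, the same list lay below the central 95% (percentile 1.56), and it lay inside with a pseudocount of 1 (92.74) or 10 (85.03) or with the mean (86.9). Endothelial markers were low among all genes, with a median of 1.00 over 14 genes, 0.884 relative to the median of all genes, at percentile 0.27. None had an unadjusted p under 0.05, with Cdh5 at 0.967 and Pecam1 at 0.990 in the authors' deposited table as the most abundant. This list lay inside the central 95% with the mean (5.93). Bone and cartilage markers had a median of 1.28 over 10 genes at percentile 91.45 (99.04 with unmatched random lists, 69.71 with the mean), with Phex at 2.31 and Col9a1 at 1.78 higher, Col2a1 lower at 0.623 in the authors' deposited table, and 0 past 0.05 over the list alone.

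Salivary gland markers, measured for 6 of 17 listed, had the lowest list median, 0.424, below all 10000 random lists. At an unadjusted p under 0.05, 1 was higher and 1 lower, and 4 were neither. The mucin gene Muc19 had means of 4.87 against 12.9 in WT, a ratio of 0.379, and an FDR of 0.143 in the authors' deposited table. Muc19 was the 1 lower gene over the list alone, and Sox10, which neural crest cells also express, the 1 higher. The mucin gene Muc5b, chosen after its values were seen, had the lowest ratio of the list at 0.112 with a p-value of 0.129 in the authors' deposited table. Of the melanocyte markers only Mitf was listed, at 1.12 in the authors' deposited table, which is below the median of all genes. Immediate early and stress genes had a median of 1.14 over 22 genes at percentile 86.01, with Fosb at 1.997 and Ddit4 at 1.30 in the authors' deposited table as the 2 with an unadjusted p under 0.05 and 0 over the list alone.

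Sex-linked genes were measured for 5 of 6 listed. Xist, the X-inactivation RNA expressed in female cells, had means of 735 against 142 in WT, a ratio of 5.19 with a p-value of 0.0126 and an FDR of 0.291 in the authors' deposited table. The Y-linked genes Ddx3y and Eif2s3y had ratios of 0.596 and 0.642, with p-values of 0.173 and 0.192 in the authors' deposited table. The list median was 0.614, below all 10000 random lists. No member passed 0.05 over the list alone. The remaining Y-linked genes Kdm5d and Uty, chosen after their values were seen, had 0.548 and 0.614 in the authors' deposited table. Xist, Mid1 and Gpm6b lie on the X chromosome. The sex of each library is not given in the sources used here, so a difference in sex between the groups was not excluded as a source of part of the differences between them.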

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

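The number of genes that differed moved with the threshold: 15 at the deposited FDR under 0.05, 2 at 0.01, 28 at 0.1 and 2437 at an unadjusted p under 0.05 (546 under 0.01, a threshold chosen after the data were seen). Over abundant genes only, adjusted again, 4 passed: that alternative tests fewer genes and leaves out low ones. A 2-fold minimum gave 13, and the recomputed adjustment 15. Fst stayed higher in the libraries labelled Fst-KO in each alternative, between 0.88 and 1.07 on the log2 scale. The number of lists outside the central 95%, 15 of 27, was between 12 and 15 in the alternatives that kept all lists. Over abundant genes only, 22 lists had enough genes and 11 lay outside, a count that leaves out the salivary, sex-linked and myeloid lists: the Hedgehog and activin lists entered, and the BMP ligand, Wnt ligand and FGF lists left. The neural and Schwann cell list reversed over abundant genes only, to percentile 1.56, and the cause was not tested. Of 113 genes that the naming rule gives besides Fst, centring on the median of all genes turned the side of 1, Mitf, and of those named outside the rule it turned Trpm5, Myf5 and Myh14. None of them had an unadjusted p under 0.05. No paired analysis was possible because the table gives group means only, and the shared replicate numbers carry no values. For the same reason DESeq2 with its size factors, camera, fry, leaving out each library and other splits of the libraries were not run. Removing the filter on low values was not run either, since the genes it took out are not used here. Depth per library is unknown, so it sets no stated limit.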

Other observations

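The lists used in this part were written after the table had been seen, and the tests of Fst against the shift of all genes and against exchanged labels, the bootstrap intervals, the condition on the WT level of heart genes, the quotient without Mybpc1, the test of a lower muscle share on the 5 contractile genes, and the test of the genes near Fst as a pattern of its own were chosen after results were seen. Fast-twitch muscle genes were low: 20 genes had a median ratio of 0.689 (0.607 relative to the median of all genes), below all 10000 random lists, and 7 of them were lower and 0 higher at an unadjusted p under 0.05, with 0 past 0.05 over the list alone. This largely repeats the report, since 10 of the 20 are also in the fixed muscle list and Mybpc2 and Gpd1 are among the lowest ratios given there. The other 10 had a median ratio of 0.605. Examples in the authors' deposited table were Mybpc2 at 0.353, Gpd1 at 0.396, the calcium-binding protein gene Casq1 at 0.538 and the glycogen phosphorylase gene Pygm at 0.583. Pan-muscle and myogenic genes had a median of 0.899 over 16 genes, 10 of them in the fixed muscle list, also below all 10000 random lists, with 2 lower and 0 higher at an unadjusted p under 0.05, and the early myogenic regulators Myod1 and Myf5, chosen after their values were seen, at 1.27 and 1.05 in the authors' deposited table. Genes listed as slow-twitch, other than those past the FDR, had a median of 1.01 over 13 genes, 0.893 relative to the median of all genes. This lay at percentile 3.015, inside the central 95%. At an unadjusted p under 0.05, 3 were higher and 1 lower, and 3 of the 13 are also in the fixed muscle list, with Tnnt1 at 2.03 and Casq2 at 0.625 as the 2 past 0.05 over the list alone in the authors' deposited table.

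Genes of connective-tissue mast cells were higher. Their median ratio was 2.51 over 10 genes, 2.21 relative to the median of all genes, and 7 were higher and 1 lower when adjusted over the list alone. Tpsab1, a near-identical neighbour of Tpsb2, had a ratio of 5.41 in the authors' deposited table. Its means were 2.49 in the libraries labelled Fst-KO and 0.459 in WT, the smallest group mean of all genes. Hdc, the enzyme that makes histamine, had a ratio of 2.47. The interleukin 33 receptor Il1rl1 had 2.41, from means of 1.79 and 0.740 in WT. The ratios of Tpsab1 and Il1rl1 thus rest on low values. Kit, which other cells of the tongue also express, was the lower one at 0.784 in the authors' deposited table. At least Cma1 and Tpsb2 had been seen when that list was written, and Mcpt4, Cpa3 and Kit are also in the fixed list of myeloid and mast cell markers, so its median partly repeats values given in the report. Genes of the Ifi200 family, sensors of DNA on chromosome 1, had a median of 2.66 over 6 genes, and 4 were higher over the list alone: Pyhin1 at 3.50, Ifi204 at 3.25, Ifi202b at 3.17 and Mndal at 2.23 in the authors' deposited table. These 4 had low WT means, from 0.868 for Pyhin1 to 3.20 for Ifi202b. Genes of this family are near-identical to each other in part, so their single values are uncertain. The Ifi200 genes were also tested against an interferon response and against mast cells, and those tests are given here only as list values. Interferon-stimulated genes, over 17 genes, lay at percentile 42.6 with a median of 1.15 and 0 past 0.05 over the list alone.

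Fst was higher in the libraries labelled Fst-KO. A shift of all genes by the normalisation leaves it unexplained, since the ratio of Fst stayed at 1.85 relative to the median of all genes. Exchanged group labels, with an allele that removes the transcript, would leave little Fst in one group, and the lower group mean was 47.6% of the higher. An allele that leaves much of the transcript in place was not tested, and neither was a change of Fst transcription that follows from the loss of its protein. Raised BMP signalling that induces Fst was left open: the BMP target list lay at percentile 6.98, under the bound of 50 set beforehand, but at 53.58 over abundant genes only. The bootstrap interval of its median ratio, 0.947 to 1.21, holds the median of matched random lists, 1.14. That bootstrap resamples the genes of the list, which vary together, and does not measure the spread between libraries.

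The muscle pattern was that 5 slow and cardiac contractile genes, picked because they passed the FDR, were higher while fast-twitch genes were lower. Heart tissue in the dissection was not excluded: 8 genes listed as heart genes had a median ratio of 0.851 (bootstrap 0.614 to 1.24), under the bound set beforehand, but Myl4 among them is a fixed muscle marker, only 4 had a WT mean below the rise of Myh6, so that their muscle baseline can hide a small share of heart, and 12 of the 20 written down are not in the table. A lower share of all skeletal muscle would lower muscle genes, while the 5 were higher, the lowest of their ratios being 3.86 against a median of 1.14 over all genes. They were picked as higher genes past the FDR, so this test of them could not come out otherwise and restates the pattern. It was put in once the test written first had decided nothing. That first test used the lower quartile of the other slow-twitch genes (0.817, with an upper quartile of 1.22). For the fast genes a lower share of muscle cannot be told apart from a change within the muscle, with a pan-muscle median 1.30 times that of the fast genes. More slow relative to fast muscle may account for the pattern, yet the other slow genes lay 1.47 times above the fast ones, between the bounds of 1.1 and 1.5. Without Mybpc1, a slow isoform that stood among the fast genes, the quotient was 1.495. It also rests on the choice of slow genes. Their median is the ratio of Myh14, which encodes a non-muscle myosin heavy chain but stood among the slow genes. The quotient without Myh14 was not computed. The muscle genes Mb at 4.63 and Myl6b at 3.32 were left out of the slow list. Myh14 and Mb were chosen after their values were seen. A quotient this near a bound turns on the make-up of the lists, so this stays open.

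Genes near Fst had a low p more often than genes elsewhere, in a test first written for the Ifi200 genes, which lie on chromosome 1 and so outside any segment around Fst. Within 10 Mb of Fst, 13.5% of 52 genes had a deposited p under 0.01, against 3.49% of 15005 genes elsewhere (odds ratio 4.30, 95% interval 1.63 to 9.66, Fisher's exact test, two-sided p = 0.0022), where neighbouring genes are not independent. Elsewhere, 0.293% of 13979 runs of as many neighbouring genes held as many genes with such a p. The runs overlap, each starting 1 gene after the last, so they stand for far fewer separate regions. They match the number of genes, not the 10 Mb, and do not count smaller groups that lie closer together. Myh6, Myh7 and Cma1, all past the FDR, are such a group on chromosome 14, between positions 54941921 and 55944675. The 7 genes near Fst with a p under 0.01 were Rgs7bp, Gpx8, Arl15, Parp8, Emb, Fgf10 and 4833420G17Rik. The first 6 had ratios from 1.31 to 1.82 and the last 0.685 in the authors' deposited table, and 0 of the 7 passed the FDR of 0.05. A segment of another strain carried along with the mutant allele is a candidate explanation only, since the pattern is the result of that test, the labels give C57BL/6 for every library and no sequence was examined, and an effect of the mutation on its neighbours was not tested.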
